A study of Caenorhabditis elegans with 6 samples.

How the data were processed

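Whole-animal total RNA of Caenorhabditis elegans, wild-type strain N2, was measured on 6 Affymetrix 1-colour arrays, 3 from animals held in buffer and 3 from animals held in buffer with C-SPIONs, which are superparamagnetic iron oxide nanoparticles coated with citrate. Per the labels' protocols, synchronised hermaphrodites grew on bacterial plates for 48 h until the L4 larval stage and then spent 24 h at 20 °C in M9 salt buffer at 50%, without particles or with 500 µg/mL of them. RNA was extracted with Trizol and 0.5 mm glass beads, cleaned on columns and treated with DNase, and 200 ng went into a whole-transcriptome amplification that gave biotin-labelled cDNA, per the labels' protocols.

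The authors' deposited values are log2 signals, 1 per transcript cluster (the probes that stand for 1 transcribed locus) and array. They were made with RMA, which corrects background, normalises arrays to each other and summarises probes, in Affymetrix Expression Console, per the submitters' processing notes; versions and settings are not given in the sources used here. The values carry 2 decimals. The source name of the third control repeats that of the second while its title counts it as the third, and the title was used. Detection calls and scanner files were not used here, so the signal over background of a cluster is unknown, and the number of arrays limits the precision. RMA compresses small changes near background, and normalisation between arrays removes any change of total RNA per animal, so all values are relative to the other transcripts of the same array.

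The table holds 29317 transcript clusters. The platform annotation paired 25546 of them with 1 gene symbol and 646 with several, and 3125 are unnamed here. Symbols were updated through gene identifiers to the RefSeq gene table of assembly WBcel235, where 25495 clusters with 1 symbol matched; no coordinates are printed, because the array's own genome build is not given in the sources used here. Control probe sets were to be left out by their identifiers, but the numeric identifiers do not show them. The 26192 clusters with a symbol were therefore tested and the unnamed ones were not, a choice made after the identifiers were seen and before any test; a fit on all clusters is among the alternatives. Clusters with several symbols were tested and never named.

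Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, two-sided, prior degrees of freedom 3.11), with Benjamini-Hochberg adjustment and a threshold of 0.05. Differences are C-SPION minus control on the log2 scale, with 95% confidence intervals from the same fit. The labels do not say whether the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

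Gene lists, 40 with at least 5 measured members, were tested with limma's camera at a preset correlation of 0.01 on 25478 genes, each represented by its brightest cluster, and the lists' p-values were adjusted together. Camera asks whether a list shifted against the other genes; fry and camera with a correlation estimated for each list were run beside it. The mean of each list was also computed per array, and its exact two-sided permutation p over the 6 arrays cannot be below 0.1.

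The lists, the tests and the rule for named genes were set before the data were examined. The rule took the 10 largest changes in each direction among clusters past the threshold with non-overlapping groups, filled to 5 in a direction by smallest unadjusted p where fewer passed; 10 sentinel genes whatever their values; and up to 4 members of each described list by smallest unadjusted p. Described lists were those that passed and 6 further lists on iron, metals, citrate, endocytosis, oxidative stress and heat shock; these 6 were chosen after list results had been seen.

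The fits were tested on simulated data with the spread of these arrays. Of 200 clusters changed among 26192, limma recovered 0% at a true 2-fold change, 59% at 4-fold and 89% at 8-fold, with 0, 3 and 7 false calls. In the real arrays limma's estimate of the share of unchanged clusters was 0.809, which leaves room for more changed clusters than were simulated. Recovery depends on that number, and the simulated residuals were independent, so these percentages need not hold for the real arrays. In 20 simulated runs on 25478 genes, camera recovered 99% of lists shifted by 0.5 on the log2 scale, with 2 false calls in all. The simulated lists held random genes with independent residuals. In the real arrays the estimated correlation was 0.593 for the mitotic and meiotic germ line list and 0.219 for the neuropeptide list. The simulation therefore does not give camera's rate of false calls on lists so correlated. The alternatives were a replicate block, leaving out each array, quantile normalisation or median centring, filters on dim clusters, other eBayes and weighting options, other thresholds, other list tests and the mean over a gene's clusters. Testing all clusters and using protein-coding genes as the background were added after seeing the data. Plots were drawn with matplotlib 3.10.9.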

Results

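The data were log2 RMA signals of 26192 named transcript clusters on 6 arrays, 3 of control animals in buffer and 3 of animals exposed for 24 h to C-SPIONs at 500 µg/mL. Pearson correlations across clusters, which are not independent replicates, ran from 0.935 to 0.969 between arrays. Control 1 correlated with C-SPION 1 at 0.959, above the 0.935 and 0.949 of C-SPION 1 with the other arrays of its own group. The medians over all clusters were 5.19, 5.04 and 5.10 for controls 1 to 3 and 5.16, 4.90 and 5.05 for C-SPION 1 to 3. No pair of arrays held identical columns, and the largest number of clusters with equal values in a pair was 293.

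The comparison of exposed with unexposed animals asked which transcripts differ after the exposure. Lists of germ line, oocyte, sperm and embryo genes were higher in the C-SPION arrays, and lists of neuropeptide, neuron, muscle and antimicrobial peptide genes were lower. Of the 40 lists, 13 passed the camera test, 6 higher and 7 lower. With an estimated correlation 0 of the 40 passed, the smallest adjusted p being 0.351, and with fry 0 passed, the smallest being 0.0691.

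No single transcript cluster passed. By limma 0 of 26192 clusters had an adjusted p under 0.05, and the smallest adjusted p was 0.201. At an unadjusted p under 0.05 there were 1368 higher and 1912 lower clusters, 3280 in all against 1310 expected with no change. The groups did not overlap in 4883 clusters, or 18.6%, where chance gives 10%. Among the clusters with the smallest p in the lower direction was pdf-2, which encodes a neuropeptide of the pigment-dispersing factor family (cluster 18610877). Its signal was 8.40 ± 0.17 in controls and 6.38 ± 0.06 with C-SPIONs (SD, n = 3), a log2 difference of -2.02 (95% interval -2.47 to -1.57, limma adjusted p = 0.201). The other 4 of the lower direction were the noncoding RNA genes W06F12.7 at -2.62 and ZK381.44 at -2.16, and F49F1.5 at -1.77 and C27A7.8 at -1.77, each with adjusted p = 0.201. In the higher direction vit-1, which encodes a vitellogenin, or yolk protein (cluster 18613465), was at 5.56 ± 0.49 in controls and 7.24 ± 0.13 with C-SPIONs (SD, n = 3), a difference of +1.68 (95% interval 1.02 to 2.34, limma adjusted p = 0.217). The others were skr-7 at +1.44, F09C6.13 at +1.41, vap-2 at +1.40 and the pseudogene rmd-4 at +1.23, with adjusted p from 0.210 to 0.217. None of these 10 genes passed, and in all 10 the 3 arrays of each group lay apart. Without C-SPION 1, 63 clusters passed, 6 higher and 57 lower, among them pdf-2 at -1.98, W06F12.7 at -2.44 and ZK381.44 at -2.32.

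Genes of the germ line were higher with C-SPIONs. The mitotic and meiotic germ line list rose 1.56-fold on average, from a mean log2 signal of 7.52 ± 0.33 to 8.16 ± 0.22 (SD, n = 3 arrays), and 38 of its 38 measured members were higher. The oocyte and eggshell list rose 1.56-fold, from 8.07 ± 0.31 to 8.72 ± 0.16, with 22 of 24 members higher. In the germ line list glp-1, the Notch receptor that keeps germ line stem cells dividing, was at 6.67 ± 0.32 and 7.58 ± 0.11, and cyb-3, a B-type cyclin, at 8.93 ± 0.09 and 9.74 ± 0.26. Further members were glh-4, a P granule helicase, at +1.04 and pgl-3, a P granule protein, at +0.86. In the oocyte list rme-2, the yolk receptor of oocytes, was at 6.41 ± 0.32 and 7.39 ± 0.26, and puf-3 at +1.15, cbd-1 at +0.79 and mex-6 at +0.73. Camera gave an adjusted p of 1.84e-13 for the germ line list and 1.91e-09 for the oocyte list. Both had adjusted p = 0.456 with an estimated correlation, the highest over the alternatives, of which the lowest were 2.18e-15 and 1.98e-10. Of the members, 21 germ line and 14 oocyte genes had an unadjusted p under 0.05, 0 and 5 passed when adjusted over the list alone, and 0 passed over all genes. Lists that passed were picked on these same values. Counts adjusted over a list alone, here and below, are therefore no separate evidence. The 3 arrays of each group lay apart for both lists.

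The sperm list rose 1.33-fold, with 49 of 59 members higher (camera adjusted p = 8.29e-05). It had adjusted p = 0.456 with an estimated correlation, and the lowest over the alternatives was 1.37e-06. Its leading members were spe-11 at +1.33, nspd-10 at +1.19, nspd-9 at +0.79 and spe-43 at +0.77. The embryo list rose by 0.38 on the log2 scale, with 55 of 73 members higher (camera adjusted p = 8.36e-05). It had adjusted p = 0.588 with an estimated correlation, and the lowest over the alternatives was 4.28e-08. Of its 4 leading members, skr-7, skr-15 and skr-13, at +1.44, +0.73 and +0.91, encode Skp1-related parts of ubiquitin ligases, and vet-6 was at +1.24. The 73 members of the embryo list include 34 sdz and 20 skr genes, so its rise alone does not show more embryo RNA. The DNA damage and apoptosis list rose 1.34-fold, with 20 of 22 members higher (camera adjusted p = 1.94e-04). It had adjusted p = 0.456 with an estimated correlation, and the lowest over the alternatives was 1.74e-05. Its leading members were msh-6, a mismatch repair gene, at +0.90, rad-51, the strand exchange recombinase, at +0.65, ced-3, the cell death caspase, at +0.58 and brd-1, the partner of the BRCA1 homologue, at +0.58. Adjusted over the list alone, 0 sperm, 1 embryo and 0 DNA damage genes passed, and 0 over all genes. The arrays of the groups overlapped for these 3 lists (exact permutation p = 0.2 for each), with C-SPION 1 apart from the other C-SPION arrays. Relative to the control mean, the sperm list stood at +0.09 in C-SPION 1, +0.54 in C-SPION 2 and +0.60 in C-SPION 3, with control 3 at +0.20. The embryo list stood at +0.04, +0.54 and +0.54, with control 3 at +0.31, and the DNA damage list at +0.15, +0.60 and +0.53, with control 2 at +0.15. In the same C-SPION arrays the germ line list stood at +0.39, +0.80 and +0.73. Control 3 was lowest on both, at -0.39 for germ line and -0.16 for DNA damage. Whether the DNA damage list rose apart from the germ line list was not tested.

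Neuronal genes were lower with C-SPIONs. The neuropeptide list, which holds FMRFamide-like and other neuropeptide genes and their processing enzymes, fell 1.64-fold on average, from 8.37 ± 0.23 to 7.65 ± 0.09 (SD, n = 3 arrays), and 54 of its 55 members were lower. The neuron list, made of synaptic, neurotransmitter and sensory genes, fell 1.62-fold, from 6.39 ± 0.30 to 5.70 ± 0.26, with 28 of 29 members lower. Beside pdf-2, the neuropeptide genes with the smallest p were flp-1 at 10.33 ± 0.09 and 9.01 ± 0.37, nlp-3 at 8.84 ± 0.02 and 7.57 ± 0.28, and flp-16 at 9.85 ± 0.15 and 8.87 ± 0.12. In the neuron list snt-1, synaptotagmin, was at 8.11 ± 0.33 and 6.60 ± 0.60, and ric-4, the SNAP-25 homologue, at 9.09 ± 0.32 and 7.68 ± 0.49. The kinesin gene unc-104 was at -1.17, and egl-3, a proprotein convertase that is also on the neuropeptide list, at -1.03. Camera gave an adjusted p of 1.63e-22 for neuropeptides and 1.91e-09 for neurons. The neuropeptide list had adjusted p = 0.351 and the neuron list adjusted p = 0.404 with an estimated correlation, the highest over the alternatives, of which the lowest were 1.26e-26 and 4.95e-12. Unadjusted p was under 0.05 for 34 neuropeptide and 12 neuron genes, all of them lower; 26 and 5 passed when adjusted over the list alone, and 0 over all genes. The 3 arrays of each group lay apart for both lists, with an exact permutation p of 0.1, the smallest that 3 against 3 arrays allow.

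Genes of antimicrobial peptides, small secreted peptides made largely in the epidermis, were lower too. That list fell 1.38-fold, from 6.75 ± 0.05 to 6.29 ± 0.10 (SD, n = 3 arrays), with 38 of 60 members lower and 11 passing when adjusted over the list alone. Its leading members were the caenacin cnc-8 at 10.53 ± 0.17 and 8.56 ± 0.36, fipr-26 at 9.15 ± 0.16 and 7.70 ± 0.02, abf-2 at -1.74 and nlp-34 at -1.37. Camera gave an adjusted p of 1.81e-05, and adjusted p = 0.351 with an estimated correlation, with 5.63e-08 the lowest over the alternatives. The correlation estimated for this list was 0.011, near the preset 0.01, so correlation between its genes does not account for the higher p. The hypodermis and seam list, the epidermal markers, stood at -0.34 and did not pass (camera adjusted p = 0.0769). Its array means relative to the control mean were +0.03 in C-SPION 1, -0.56 in C-SPION 2 and -0.49 in C-SPION 3, and without C-SPION 1 it passed at -0.52. The body wall and pharyngeal muscle list fell 1.29-fold, with 26 of 30 members lower (camera adjusted p = 7.24e-05). It had adjusted p = 0.456 with an estimated correlation, and the lowest over the alternatives was 3.80e-06. Without control 2 its shift was -0.24 in place of -0.37. The myosin heavy chain genes myo-2, myo-1 and unc-54 were at -0.75, -0.71 and -0.49 and unc-15, paramyosin, at -0.65; adjusted over the list alone 0 muscle genes passed.

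**Figure D1:**
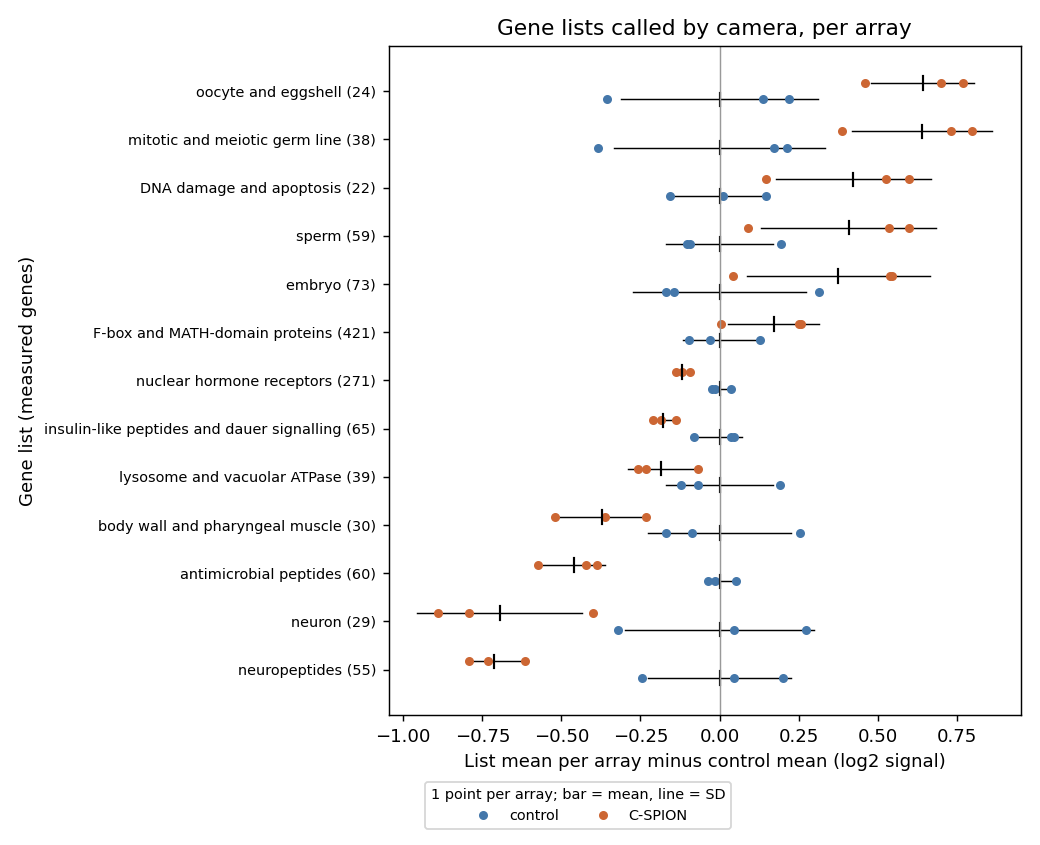
Mean of each of the 13 lists that passed camera, per array, minus the control mean of that list (log2 signal, horizontal axis), with 1 point per array, a bar at the group mean and a line of 1 SD to each side. The C-SPION arrays lie between -0.79 and -0.62 for neuropeptides and between 0.39 and 0.80 for the mitotic and meiotic germ line, apart from the controls in both.

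The remaining 4 lists that passed moved less. The lysosome and vacuolar ATPase list fell 1.14-fold, with 31 of 39 members lower (camera adjusted p = 0.010, and adjusted p = 0.588 with an estimated correlation). Its leading members were glo-3, a gut granule gene, at -1.26, the proton pump genes vha-5 and vha-13 at -0.64 and -0.44, and aman-1, an alpha-mannosidase, at +0.58. The insulin-like peptide and dauer signalling list fell 1.13-fold, with 39 of 65 lower (camera adjusted p = 0.0150, and adjusted p = 0.404 with an estimated correlation). It was led by the insulin-like peptide genes ins-30 at -1.32, ins-1 at -0.98, ins-35 at -0.85 and ins-22 at -0.84. The nuclear hormone receptor list fell 1.08-fold, with 166 of 271 lower (camera adjusted p = 0.0203, and adjusted p = 0.351 with an estimated correlation). It was led by nhr-115 at -1.09, nhr-143 at -1.04, nhr-107 at -0.92 and nhr-101 at -0.74. The F-box and MATH-domain list rose 1.13-fold, with 263 of 421 higher (camera adjusted p = 0.0324, and adjusted p = 0.588 with an estimated correlation). By symbol stem, a grouping chosen after the data were seen, fbxb genes stood at +0.49 (93 of 108 higher) and fbxc genes at +0.39 (33 of 44 higher), while the 188 fbxa genes stood at -0.043 (102 lower) and did not pass (camera adjusted p = 0.370), turning to +0.047 after median centring. With an estimated correlation adjusted p was 0.673 for fbxb and 0.639 for fbxc. C-SPION 1 stood at +0.0059 on the F-box and MATH-domain list relative to the control mean, below control 3 at +0.13. Of its leading members fbxb-102, fbxb-57 and fbxc-50 were at +1.58, +1.46 and +1.04 and fbxa-105 at -1.01. The lysosome call was lost without control 2, C-SPION 1 or C-SPION 3, with shifts of -0.090, -0.16 and -0.15, and the insulin call without control 2, at -0.16. The receptor call was lost without control 2 or C-SPION 3, at -0.10 and -0.11, and the F-box call without control 1, control 2, C-SPION 2 or C-SPION 3, at 0.16, 0.12, 0.13 and 0.13. With each array centred on its median the shifts were -0.096, -0.088, -0.027 and 0.26 for these lists in the same order. Over the alternatives their lowest adjusted p were 3.62e-04, 0.00335, 4.69e-04 and 0.00212, and the values with an estimated correlation were the highest. The estimated correlation itself was 0.010 for the insulin list and 0.005 for the receptor list, not above the preset 0.01. For these lists correlation between genes does not account for the higher p. Adjusted over the list alone, 1 lysosome gene and 0 genes of the other 3 lists passed, and 0 over all genes.

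Iron and metal genes did not pass as lists. The iron and haem handling list stood at -0.20, with 10 of 17 members lower (camera adjusted p = 0.200), and metal detoxification at -0.21, with 13 of 17 lower (camera adjusted p = 0.10). For metal detoxification the 3 arrays of each group lay apart (exact permutation p = 0.1). This held for 14 of the 40 lists, of which 8 passed camera. The ferritin gene ftn-1, whose product stores iron, was at 8.99 ± 0.34 in controls and 9.43 ± 0.16 with C-SPIONs (SD, n = 3), a difference of +0.44 (95% interval -0.11 to 1.00, limma adjusted p = 0.479), and +0.25 without control 2. The second ferritin gene ftn-2 was at +0.05 (95% interval -0.43 to 0.53) and smf-3, an intestinal iron and manganese transporter, at +0.17 (95% interval -0.40 to 0.74). The haem-responsive genes hrg-6, hrg-3, hrg-7 and hrg-4 were at -1.42, -1.24, -0.80 and -0.53, with adjusted p from 0.262 to 0.473; 1 gene of the iron list passed when adjusted over the list alone. The metallothionein genes mtl-1 and mtl-2, which bind heavy metals, were at +0.11 (95% interval -0.39 to 0.61) and -0.06 (95% interval -0.48 to 0.37), and mtl-2 was at +0.03 after median centring. The cadmium-responsive gene cdr-1 was at -0.26 (95% interval -0.89 to 0.38), cdr-2 at -1.56, cdr-4 at -0.96, mrp-1 at -0.65 and numr-1 at +0.95, none past the threshold. Several of these values rested on single arrays. Without control 3, cdr-4 was at -0.52, hrg-7 at -1.25, cdr-1 at -0.45, mtl-1 at +0.26, mtl-2 at -0.0033, ftn-2 at +0.14 and the iron and haem handling list at -0.13. Without control 2, mtl-1 was at -0.010, mtl-2 at -0.11 and cdr-1 at -0.08, and without control 1, hrg-7 was at -0.46, ftn-2 at -0.020 and smf-3 at +0.07. Without C-SPION 1 the iron and haem handling list was at -0.13, smf-3 at +0.37 and ftn-2 at +0.13, without C-SPION 2 ftn-2 was at -0.047, smf-3 at +0.08 and cdr-1 at -0.085, and without C-SPION 3 smf-3 was at +0.06 and mtl-2 at -0.028.

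Citrate and uptake genes did not pass as lists either. The citrate transport and TCA cycle list stood at +0.09, with 17 of 27 members higher (camera adjusted p = 0.331), and was led by sdha-2 at +0.75, aco-2 at +0.47, sucl-2 at +0.43 and sucg-1 at +0.35. Endocytosis and membrane trafficking stood at +0.09, with 20 of 34 higher (camera adjusted p = 0.285), led by rme-6 at +0.61, cav-1 at +0.60, vps-35 at +0.56 and cav-2 at -0.46. No gene of these lists passed. The citrate transport and TCA cycle list was at +0.19 without control 2, +0.17 without C-SPION 1, +0.030 without control 3 and +0.015 without C-SPION 2. Endocytosis and membrane trafficking was at +0.15, +0.057 and +0.035 without control 2, control 3 and C-SPION 2. Without control 3, vps-35 was at +0.24 and aco-2 at +0.26, and without C-SPION 2 sucl-2 was at +0.26.

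Stress genes were heterogeneous. The oxidative stress defence list stood at -0.07 (camera adjusted p = 0.399), or +0.02 after median centring. Its members sod-3 and sod-4, superoxide dismutase genes, were at -0.83 (95% interval -1.62 to -0.04, limma adjusted p = 0.380) and -0.71, trx-1 at -0.95 and gpx-7 at +0.61, and gst-4, a glutathione S-transferase gene, at -0.36 (95% interval -0.86 to 0.14). The heat shock list stood at +0.23 (camera adjusted p = 0.401), and without control 3 it passed at +0.42. The small heat shock gene hsp-16.2 read 8.64, 9.26 and 11.70 in controls 1 to 3 and 11.42, 11.47 and 11.65 in the C-SPION arrays, a difference of +1.65 (95% interval -0.06 to 3.35, limma adjusted p = 0.411). The heat-inducible hsp-70, chosen after its values were seen, read 3.64, 3.72 and 7.15 in controls and 6.15, 6.74 and 7.05 with C-SPIONs, a difference of +1.81 (95% interval -0.33 to 3.95, limma adjusted p = 0.455). Without control 3 the differences were +2.56 for hsp-16.2 and +2.97 for hsp-70, still not past the threshold. Without control 1 the heat shock list was at +0.07, hsp-16.2 at +1.03 and gst-4 at -0.23, and the oxidative stress defence list was at +0.020 without C-SPION 1 and -0.15 without C-SPION 2. Other members were hsp-1 at +0.42, hsp-12.2 at -0.51 and hsp-12.3 at -0.54. The yolk protein gene vit-2 was at +0.07 (95% interval -0.40 to 0.55), or -0.028 without control 2, +0.19 without control 3 and +0.047 without C-SPION 1, and the vitellogenin list stood at +0.57 (camera adjusted p = 0.0814) and passed without control 3 at +0.76.

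**Figure D2:**
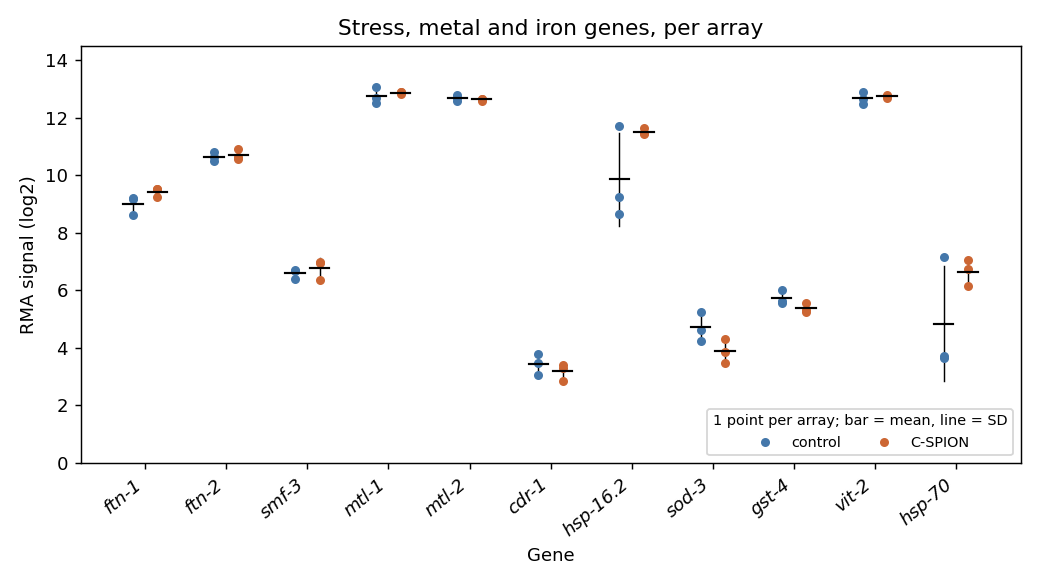
Signal per array (log2 RMA, vertical axis starting at 0) of the 10 sentinel genes and hsp-70 in control and C-SPION arrays, with 1 point per array, a bar at the group mean and a line of 1 SD to each side. Control 3 lies at 11.70 for hsp-16.2 and at 7.15 for hsp-70, above the other controls and near the C-SPION arrays.

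The other lists did not pass. On the side of immunity and detoxification, mean shifts were -0.19 for pathogen response genes, -0.07 for lysozymes and saposin-like proteins, +0.03 for C-type lectins (+0.048 without control 1, +0.0075 without control 3 and +0.016 without C-SPION 1), -0.11 for UDP-glycosyltransferases and glutathione S-transferases, and -0.0032 and -0.0025 for cytochrome P450 and ABC transporter genes. Pathogen response genes passed without C-SPION 2, at -0.26, and with the dimmest 50% of clusters left out, at -0.57, but not with the dimmest 25% left out, and stood at -0.12 without C-SPION 1; the transferases passed without control 1, at -0.16, and stood at -0.030 without control 2 and -0.066 without C-SPION 1. In proteostasis, shifts were -0.16 for the endoplasmic reticulum unfolded protein response, +0.19 for mitochondrial chaperones and proteases, +0.03 for autophagy and +0.02 for digestive and lysosomal proteases, and the first of these passed without C-SPION 1, at -0.23. In metabolism, shifts were +0.11 for fasting lipid use and lipases, which passed without C-SPION 1 at +0.18 and stood at +0.065 without C-SPION 2, and +0.15 for fatty acid synthesis and desaturation, which passed without control 2 at +0.21. The mitochondrial respiratory chain stood at +0.01, cytosolic ribosomal proteins at +0.04, or +0.023 without control 1 and +0.024 without C-SPION 1, and the hypoxia and hydrogen sulphide response at -0.29, or -0.15 without control 3. Cuticle collagens stood at -0.19, or -0.13 without C-SPION 3, and moulting at -0.16, the latter passing without C-SPION 1 at -0.23. The intestine markers stood at -0.25, with 14 of 21 lower, and the coelomocyte markers at -0.35, passing without control 3 at -0.45. The median of the digestive proteases was -0.0067 and that of the respiratory chain -0.0067, both opposite in sign to their means, and that of the cuticle collagens 0.0067; camera's direction was down for the proteases and the collagens and up for the respiratory chain. Leaving out control 1 turned the sign of the digestive proteases (-0.035), cytochrome P450 (0.012), autophagy (-0.012) and the respiratory chain (-0.040), and leaving out control 2 that of the ABC transporters (0.082). Leaving out C-SPION 1 turned lysozymes (0.020), cytochrome P450 (0.0046) and ABC transporters (0.027), and leaving out C-SPION 2 the proteases (-0.012), autophagy (-0.018) and the respiratory chain (-0.038).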

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

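The alternatives were planned except 2 chosen after seeing the data, namely testing all clusters and using protein-coding genes only, which gave 0 clusters and 13 lists. The count of clusters stayed 0 under all settings run except leave-one-out, where it ran from 0 to 63, the 63 arising without C-SPION 1. The smallest limma adjusted p of the main fit was 0.201. The other thresholds, on adjusted p or fold change, used that fit and could give only 0. The count of lists was 13 to 15 in the other settings with camera at the preset correlation, 10 to 16 in leave-one-out, 0 with an estimated correlation and 0 with fry. Whether the replicate numbers pair the arrays was not settled. Deviations from the group means correlated at 0.222, 0.203 and 0.008 for the same numbers 1, 2 and 3. For different numbers they ran from -0.266 to 0.058. C-SPION 3 correlated more with control 1, at 0.019, than with control 3. With the replicate block 0 clusters and 13 lists passed.

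The 13 lists that passed kept their direction under all 12 other settings. The other list tests, the replicate block and the eBayes options leave a list's mean shift unchanged. Only the remaining settings could have turned a direction. With the dimmest 50% left out the shifts were -0.75 for antimicrobial peptides, 0.68 for sperm and -0.23 for nuclear hormone receptors, and with the dimmest 25% left out -0.18 for the receptors. Hypodermis markers passed after median centring, at -0.25, and with array weights, at -0.44, and vitellogenins with array weights, at 0.67. Median centring moved the median of all clusters by 0.09 and quantile normalisation by -0.0072.

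Signs that reversed all belonged to lists and genes near 0 that did not pass, and the cause was not tested. Over leave-one-out the shifts ran from -0.035 to 0.083 for digestive proteases, -0.156 to 0.020 for lysozymes, -0.012 to 0.012 for cytochrome P450, -0.065 to 0.082 for ABC transporters, -0.152 to 0.020 for oxidative stress, -0.018 to 0.0825 for autophagy and -0.040 to 0.068 for the respiratory chain. For genes they ran from -0.047 to 0.14 for ftn-2, -0.010 to 0.26 for mtl-1 and -0.028 to 0.192 for vit-2. Quantile normalisation gave 0.0048 for ABC transporters. Centring gave 0.015 for lysozymes, 0.087 for cytochrome P450, 0.088 for ABC transporters, 0.016 for oxidative stress and 0.033 for mtl-2. Leaving out the dimmest 50% gave -0.050 for digestive proteases and -0.146 for C-type lectins, and leaving out 25% gave -0.0096 and -0.067. Leaving out cross-hybridising probe sets was not run, because the identifiers do not mark them. Without a measure of background, which dim clusters were detected is unknown.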

Other observations

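All tests below were chosen after the results they bear on had been seen, except the count of gene lists over other splits of the arrays. Genes were also grouped by the stem of their symbol, 173 families of at least 10 genes, of which 51 passed camera, 15 higher and 36 lower; with an estimated correlation the smallest adjusted p was 0.376, so 0 passed. Nucleoporin genes (npp), whose products build the nuclear pore, rose by 0.61 on the log2 scale, from 7.19 ± 0.23 to 7.80 ± 0.24 (SD, n = 3 arrays), with 26 of 26 members higher (camera adjusted p = 1.82e-10, and adjusted p = 0.639 with an estimated correlation). Non-ATPase genes of the proteasome's regulatory particle (rpn) rose by 0.58, with 13 of 13 higher (camera adjusted p = 3.92e-06, and adjusted p = 0.639 with an estimated correlation). The germ line list moved the same way, by 0.64 with 38 of 38 higher, and whether these families rose apart from it was not tested. Translation initiation factors (eif) rose by 0.35, with 20 of 23 higher (camera adjusted p = 5.71e-04, and adjusted p = 0.673 with an estimated correlation). The arrays of the groups overlapped for eif, and whether it rose apart from the germ line list was not tested either. Transthyretin-related genes (ttr) fell by 0.37, with 43 of 58 lower (camera adjusted p = 1.81e-06, and adjusted p = 0.639 with an estimated correlation), and globin-related genes (glb) by 0.45, with 30 of 34 lower (camera adjusted p = 1.30e-06, and adjusted p = 0.639 with an estimated correlation). The nssp genes fell by 0.68, with 80 of 84 lower (camera adjusted p = 2.97e-23, and adjusted p = 0.376 with an estimated correlation). Haem-responsive genes (hrg) fell by 0.50, from 6.37 ± 0.14 to 5.88 ± 0.03, with 9 of 13 lower (camera adjusted p = 0.00991, and adjusted p = 0.639 with an estimated correlation); 6 of the 13 are also on a fixed list. These directions held after quantile normalisation and after median centring.

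Germ line lists were higher while neuropeptide, neuron and muscle lists were lower. If germ line RNA only diluted all somatic RNA evenly, somatic lists would fall alike. Neuropeptides fell further than intestine markers, by a difference of -0.46 (95% interval over arrays -0.69 to -0.23), which argues against even dilution for them. That interval does not allow for neuropeptides having the largest fall of the 40 lists. The muscle and hypodermis lists were not set against them. For neurons the difference from intestine markers was -0.44 (-0.94 to 0.05). Even dilution cannot be told apart there, because the interval over arrays reaches 0 while that over genes, -0.71 to -0.17, does not. For muscle the difference was -0.12 (-0.36 to 0.11). Beside a muscle shift of -0.37 this interval is too wide to decide. Of the 21 intestine markers, 7 are on other lists too. For the germ line, 10000 random lists matched on signal shifted by 0.0084 on average (-0.17 to 0.17, observed 0.64). For neuropeptides they shifted by 0.0063 (-0.14 to 0.14, observed -0.71). In the normalised values, other genes of like signal thus did not shift as these lists did. Normalisation between arrays evens out shifts shared by genes of like signal, so this outcome was largely set beforehand. Distortion that depends on signal is therefore left undecided. The ranges come from random genes and do not allow for correlation within a list. A different make-up of tissues or a different stage of growth in the exposed animals may remain, and the C-SPION exposure itself stays open and untested; the brightest germ line gene, gld-1, went from 9.57 to 9.98 and the brightest neuron gene, snb-1, from 10.05 to 9.72.

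Neuropeptide and antimicrobial peptide genes are short, with a median span of 1492 and 418 bases against 2069 for protein-coding genes, introns included. Random protein-coding lists matched on span and signal shifted by -0.033 for neuropeptides (-0.18 to 0.10, observed -0.71). For antimicrobial peptides they shifted by -0.10 (-0.26 to 0.05, observed -0.47). A short gene span is thus argued against as the whole cause. Transcript lengths were not available, and span counts introns, so loss of short transcripts itself stays undecided. Less neuronal RNA in the exposed samples could lower neuropeptides as much as other neuronal genes; the difference was -0.026 (95% interval over arrays -0.55 to 0.50), too wide to decide. The antimicrobial list differed from the hypodermis list, the epidermal markers, by -0.12 (-0.81 to 0.57), also too wide to decide; those markers stood at a mean of -0.34 and went both ways, and in C-SPION 1 they stood at 0.03 where the antimicrobial list stood at -0.57. The exposure stays open and untested for both lists.

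In control 3 hsp-16.2 and hsp-70 stood at the level of the C-SPION arrays, 11.70 and 7.15. A wrong label or a swap is left open by a placement test. It used the 500 genes with the smallest p in the other 5 arrays, where 0 is their control mean and 1 their C-SPION mean. Left out in the same way, C-SPION 1 to 3 stood at 0.303, 0.598 and 0.769, and control 3 stood within that range, at 0.545. Control 1 also stood within that range, at 0.352, and control 2 below it, at 0.185. C-SPION 1 thus lay nearer the control end than controls 1 and 3, so the test leaves its label open too. Against a wrong label, control 3 correlated across clusters with controls 1 and 2 at 0.953 and 0.956 and with C-SPION 1 to 3 at 0.942, 0.939 and 0.939, but correlation does not always follow the groups, since C-SPION 1 correlated more with control 1, at 0.959, than with C-SPION 2 and 3, at 0.935 and 0.949. Of the lists that passed, all picked for a difference between the labelled groups, control 3 lay within the C-SPION arrays on sperm (0.20 against 0.09 to 0.60, relative to the control mean), embryo (0.31 against 0.04 to 0.54), F-box (0.13 against 0.0059 to 0.26) and lysosome (-0.12 against -0.26 to -0.067), and outside them on muscle (-0.17 against -0.52 to -0.23), neuron (-0.32 against -0.89 to -0.40), insulin-like (-0.08 against -0.21 to -0.14), nuclear hormone receptor (-0.01 against -0.14 to -0.09), neuropeptide (-0.24 against -0.79 to -0.62), DNA damage (-0.16 against 0.15 to 0.60), germ line (-0.39 against 0.39 to 0.80), oocyte (-0.36 against 0.46 to 0.77) and antimicrobial peptides (0.05 against -0.57 to -0.39). Warmth or other handling of control 3 may have raised its heat shock genes and was not tested, and a response to C-SPIONs stays open too, since both genes were higher in the C-SPION arrays than in controls 1 and 2.

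The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The count of clusters past the threshold was 0 in the real split and 0 in the highest of the others; with a real count of 0 all 10 splits must have as many, so this count says nothing about chance. The count of lists was 13 in the real split and 13 in the highest of the others, which set control 1, C-SPION 2 and C-SPION 3 against the rest, so 2 of the 10 had as many. At an unadjusted p under 0.05 the real split gave 3280 clusters and the highest other 2260.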
